A study of Mus musculus with 6 samples.

How the data were processed

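Messenger RNA of whole splenic B cells was measured on 6 Affymetrix MG_U74Av2 arrays, 2 each for wild type CBA, Xid and Btk KO mice. The deposited table holds 1 linear intensity per probe set and array, without detection calls. The software and the method that summarised the probes are not given in the sources used here. The deposited intensity values were already scaled by the authors: the 2% trimmed mean was 100.06 on each of the 6 arrays, as a global scaling to a target of 100 gives. No further scaling was applied. The header files of the scanner were used for the chip lot and the hybridisation day, and their other settings were not used here.

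The array holds 12488 probe sets, of which 66 are controls. The probe annotation gives 1 gene symbol to 10833 of the others, several to 396 and none to 1193. Through the gene number, 10817 symbols were updated or found in a gene table of the assembly GRCm38.p6, which served for names and neighbouring genes only. Intensities were taken to log2 after a pseudocount of 6, the 20th percentile of all values, was added. Probe sets whose mean log2 value over the 6 arrays lay below the 40th percentile, a mean intensity of about 19.8, were left out as dim. This removed 4969 probe sets and kept 7453, which stand for 5596 named genes.

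The 3 pairwise comparisons and the mean of both mutant lines against CBA were tested in 1 model of the 3 group means with limma (lmFit, and eBayes with an intensity trend; limma 3.58.1, R 4.3.3). This leaves 3 residual degrees of freedom, which the groups share. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 7453 probe sets at a threshold of 0.05. Of 30 gene lists for B cell biology and for other cell types of the spleen, 27 had at least 3 measured genes and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Each gene entered by the brightest of its kept probe sets. Camera with an estimated correlation and limma's fry, which asks whether a list moves one way on balance, were run beside it. With an estimated correlation no list passed, even where the estimate lay below the preset 0.01. For neutrophil markers in Btk KO against CBA it was -0.027, and the camera adjusted p went from 7.1e-08 to 0.24. A call lost in this way therefore does not by itself show correlation among the genes. In the same comparison 0.24 was also the value for macrophage markers (estimate 0.57, camera adjusted p = 7.0e-25 at the preset). Oxidative phosphorylation, which did not pass at the preset (estimate -0.0022, camera adjusted p = 0.14), had 0.24 too. The test with an estimated correlation therefore hardly told lists apart, and its values do not decide on a single list. How far the 3 residual degrees of freedom limit that test was not tested. Adjusted p-values of single members over the list alone came from the same limma fit. Levels are means with their SD (n = 2) on the intensity scale, and changes are log2 differences with their standard error. Where a group mean lies near the floor, below about 19.8, the size of a log2 difference depends on the pseudocount. Figures were drawn with matplotlib 3.10.9.

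The groups, the tests, the filter, the pseudocount, the gene lists, the rule for naming genes and all alternatives but 1 were chosen before the data were examined. The rule names Btk, and for each comparison up to 12 higher and 12 lower genes that passed the threshold with both arrays of a group above both of the other. A direction with fewer than 5 such genes was filled up to 5 by the smallest p. The rule further names up to 4 members of each described list with the smallest p, and the lineage markers Cd79a, Ms4a1, Cd3e, Lyz2, Hba-a1 and S100a8. A further marker of that rule is not reported here. Genes named outside the rule are marked in the text. No gene was named from a probe set with several symbols or none, and such probe sets are told apart in the text by their values.

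The replicate numbers mark a shared run. The design label says that a first set of 3 chips was followed by 3 chips with new RNA from new mice, and per the file headers the 3 arrays numbered 1 came from 1 chip lot and the 3 numbered 2 from another. The arrays numbered 2 were hybridised on 1 day. Of those numbered 1, CBA and Xid shared a day and Btk KO was hybridised alone on another day. Across probe sets, deviations from the group mean were correlated between groups within a run, at 0.31 for CBA with Xid, 0.37 for CBA with Btk KO and 0.44 for Xid with Btk KO. Results of a model with the run as a block are given where they change a call, and medians within each run are given beside the pooled ones for lists that passed with all arrays. Each run holds 1 array per group.

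The alternatives were the block, quantile normalization, median centring, smaller and larger pseudocounts, no filter and a stricter filter, no intensity trend, only the groups compared, each array left out, and the other tests of lists. The alternative that combines the block with leaving out the Btk KO array of run 1 was chosen after seeing the data. The steps were tested on simulated data built from the 7453 probe sets. Of probe sets changed by 1 on the log2 scale, 30.6% were recovered for Xid against CBA, 30.7% for Btk KO against CBA and 28.9% for Btk KO against Xid. At a change of 2 the shares were 92.7%, 91.8% and 92.7%, and 7.69%, 6.62% and 6.41% of the calls were false. A list of 20 genes shifted by 0.5 was recovered in 100% of the draws for Xid against CBA, and 0% of the unshifted lists were called. These draws used independent probe sets, so they do not measure what correlated genes do to camera.

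For the patterns weighed at the end, medians over genes were bootstrapped. In those tests an explanation was excluded only where the bootstrap interval lay beyond 0 and, for the share of B cells, where the mean of both runs also exceeded the SD between the runs. For the immunoglobulin segments the interval also had to hold for Btk KO of run 2 against both CBA arrays. These added conditions were chosen after the values were seen. They moved both Btk KO tests of the share of B cells from excluded to open. The tests of the sex-linked genes rest on 1 probe set each without an interval: Eif2s3x was excluded where it differed from CBA by under 1 on the log2 scale in both runs, a limit set beforehand.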

Results

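Gene expression was measured in whole splenic B cells of adult mice on 6 arrays, 2 for each of 3 groups. The groups were wild type CBA, Xid and Btk KO. Btk is the Tec family kinase that relays signals of the B cell receptor. Xid mice are the CBA/N strain, whose Btk carries the R28C substitution. The line labelled Btk KO had been crossed to CBA for 9 generations. The labels say that the second set of 3 chips used new mice, but not whether an RNA came from 1 animal or from a pool. Per array, the median intensity lay between 32.7 and 37.7 (scaled units). The number of arrays limits the precision of every value below.

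The Btk KO array of run 1 stood apart in RNA quality. Its 3' to 5' ratio was 10.4 for the Gapdh controls and 3.61 for the beta-actin controls, against at most 1.61 and 1.66 on the other 5 arrays. Its Gapdh 5' intensity was 113.8, against 819.1 to 2263.8 elsewhere. That array was also hybridised on a day of its own.

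**Figure D1:**
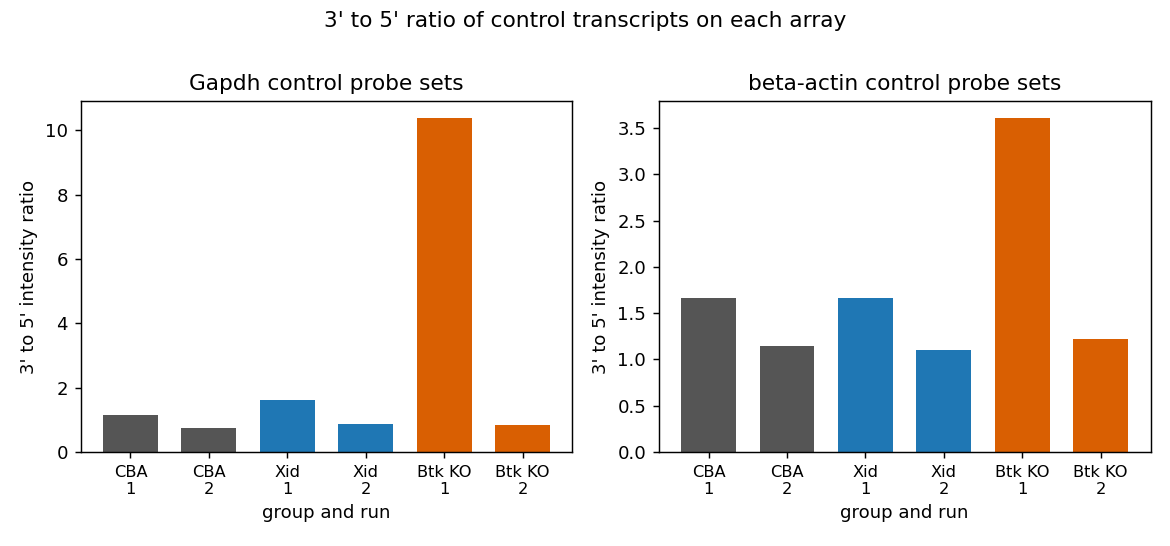
Bars show the 3' to 5' intensity ratio of the Gapdh controls (left) and the beta-actin controls (right) on each array, by group and run. Btk KO of run 1 stands at 10.4 and 3.61, and the other arrays lie at or below 1.61 and 1.66.

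Btk itself was the first transcript examined. Its brighter probe set measured 812 ± 87.9 in CBA, 742 ± 139 in Xid and 225 ± 72.5 in Btk KO (mean ± SD, n = 2 each), so the Btk KO level was 27.7% of CBA. Both Btk KO arrays, at 276.1 and 173.6, lay below all 4 arrays of the other groups, at 643.9 to 874.1. Against CBA the difference was -1.86 ± 0.27 on the log2 scale (SE), with limma adjusted p = 0.052 without the run block and 0.0053 with it. Within the runs it was -1.64 and -2.07. The Xid transcript differed from CBA by -0.14 ± 0.27. The other Btk probe set read at most 7.5 on any array and carries no information. Where the probes of the brighter set lie relative to the deleted part of the gene is not known here, and a probe outside that part would not check the knockout.

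**Figure D2:**
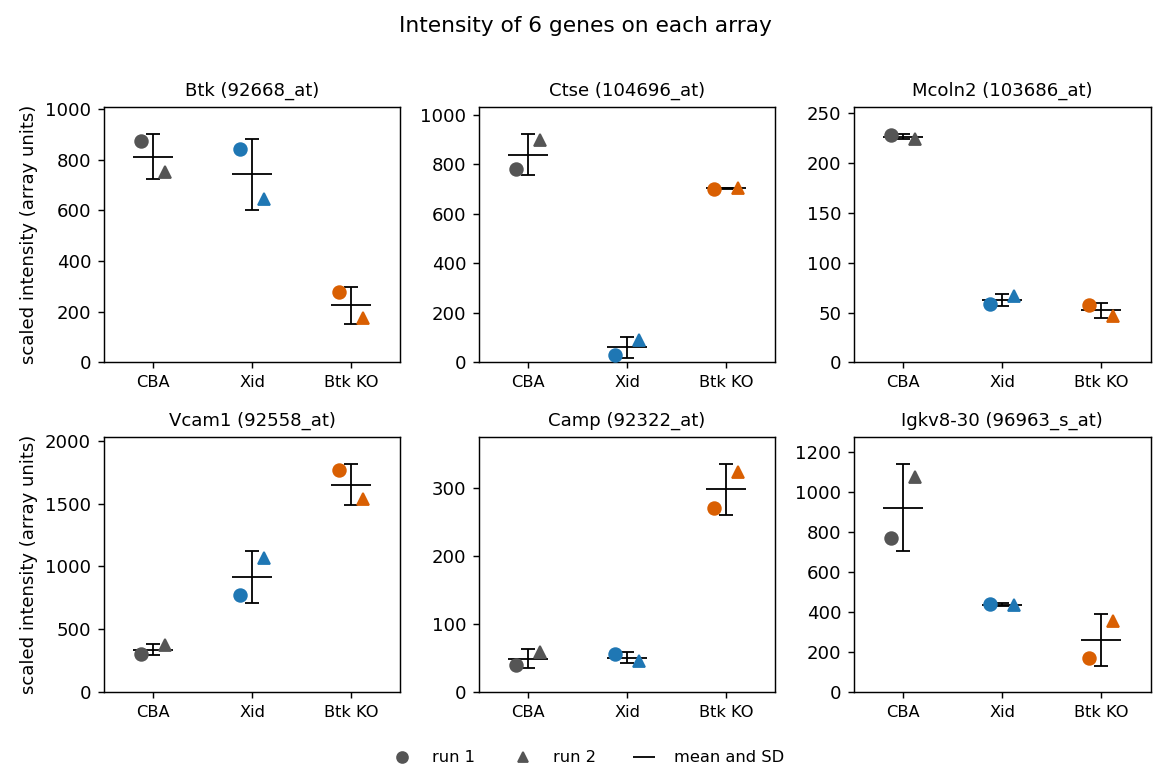
Points show the scaled intensity of 6 genes on each array (circle, run 1; triangle, run 2), with the group mean and SD (n = 2 per group). Btk is lowest in Btk KO (mean 225), the plotted Ctse probe set is lowest in Xid (61.6), Mcoln2 is low in both lines, and Camp is high in Btk KO alone (298).

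The comparison of Xid with CBA asks how transcripts of splenic B cells differ in mice with a point mutation of Btk. Xid is a strain of its own, CBA/N, so the mutation and other differences between the strains cannot be told apart. Macrophage transcripts were higher, immunoglobulin transcripts were lower, and a small number of single probe sets changed by a large factor. For the macrophage and immunoglobulin lists adjusted p = 0.33 and 0.34 with an estimated correlation. The signal of 1 of 3 probe sets for Ctse, the endosomal protease cathepsin E, fell from 839 ± 81.2 in CBA to 61.6 ± 42.6 in Xid, a change of -3.80 ± 0.40 (adjusted p = 0.032, lower in both runs). This probe set was named after its values were seen. The other Ctse probe sets, 1 of which is brighter, differed by -0.29 and -0.05. A sequence difference of the CBA/N strain under the probes was not tested and could give the same signal, so a loss of the Ctse transcript is not shown. Mcoln2, a lysosomal cation channel, measured 62.6 ± 5.66 against 226 ± 2.55, a difference of -1.76 ± 0.22 that passed with the run block (adjusted p = 0.019) and not without it (0.058).

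Without the block, limma called 5 of 7453 probe sets in Xid, 1 higher and 4 lower, with 330 at an unadjusted p under 0.05. By chance 373 would be expected there, so small p-values were not in excess in that fit. With the run block limma called 36, 27 higher and 9 lower, and 604 had an unadjusted p under 0.05. Besides Ctse, 3 of the first 5 have no symbol. They fell by 4.24, 2.45 and 3.24 on the log2 scale, from 1460 to 71.6, from 2190 to 396 and from 224 to 18.6. A probe set with several symbols rose from 10.5 ± 1.27, near the floor, to 310 ± 114, and the log2 size of 4.21 depends on the pseudocount. The next ranked genes did not pass without the block. Tspan4, a tetraspanin, measured 90.6 against 14.4 in CBA, near the floor, and Abcc3, an organic anion transporter, 165 against 50.6. Glipr2, Gatm and Hfe, the iron regulator, differed by 2.03, 1.55 and 1.74. On the lower side, a probe set annotated to Notch4, of a type that can read several related transcripts, differed by -2.97, the chemokine receptor gene Ccr1 by -1.75 and Ephx1, the microsomal epoxide hydrolase, by -2.64. With the run block these 8 genes had adjusted p between 0.019 and 0.044. Cd200, at -1.44, did not pass in either fit. The B lineage markers Cd79a and Ms4a1 differed by -0.19 and 0.04, Cd3e of T cells by -0.16, Lyz2 of myeloid cells by 0.26, Hba-a1 of red cells by 0.29 and S100a8 of neutrophils by 0.00.

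Macrophage and monocyte markers moved most among the lists in Xid. Their 23 measured genes had a median of 0.90, or 0.85 and 1.04 within the runs, and 21 were higher in both runs (camera adjusted p = 6.1e-23). For this list adjusted p = 0.33 with an estimated correlation. None passed over all genes without the block (0, with limma), 8 did with it, and 12 rose when adjusted over the list alone. Mrc1, the mannose receptor, measured 122 ± 32.7 against 37.9 ± 0.707. Vcam1, an adhesion molecule, measured 917 ± 208 against 337 ± 46.1, Spic, a transcription factor of red pulp macrophages, 182 against 65.1, and Sirpa 293 against 140. With the run block Mrc1, Vcam1 and Spic rose over all genes (adjusted p = 0.045, 0.034 and 0.034).

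Immunoglobulin segments were lower in Xid, with a median of -0.63 over 25 genes (adjusted p = 2.1e-07; adjusted p = 0.34 with an estimated correlation). Within the runs the medians were -0.50 and -0.75, and 21 were lower in both. No segment passed over all genes or when adjusted over the list alone (0, with limma); with the run block, 11 fell and 1 rose when adjusted over the list alone. Igkv8-30 measured 436 ± 6.01 against 921 ± 218, and Igkv8-19 measured 1200 against 2090. Probe sets of related segments can share signal, so single segments are uncertain.

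Genes of B cell receptor signalling had a median of -0.15 over 30 genes, at -0.11 and -0.21 within the runs (adjusted p = 0.025; adjusted p = 0.33 with an estimated correlation). Nfatc1, the calcium-dependent factor downstream of the receptor, measured 142 ± 49.1 against 451 ± 181, a difference of -1.61 that passed with the run block alone (adjusted p = 0.019). It was the single member to pass in either fit. Cd22, Cd72 and Blk differed by -0.40, -0.45 and -0.56. Marginal zone markers had a median of -0.07 over 12 genes and a mean of -0.24 (adjusted p = 0.044; adjusted p = 0.34 with an estimated correlation). Their run medians, -0.31 and 0.12, had opposite signs. Cd9 and S1pr3 fell with the run block when adjusted over the list alone, by 1.38 and 0.86. Immature and transitional markers had a median of 0.25 over 17 genes, at 0.30 and 0.24 within the runs (adjusted p = 0.025; adjusted p = 0.33 with an estimated correlation). In that list 4 rose and 1 fell with the run block when adjusted over the list alone and 0 without it, and a second Vpreb3 probe set had the opposite sign (-0.58). Cnn3, Vpreb3 and Ly6d differed by 0.72, 0.59 and 0.68, and Rag1 by -1.38.

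Further lists passed camera in Xid and lost the call with an estimated correlation; values after each median are those of run 1 and run 2. Immediate early and handling stress genes had a median of 0.38 over 31 genes, at 0.64 and 0.10 (adjusted p = 1.4e-04; adjusted p = 0.42 with an estimated correlation). Proliferation genes had a median of -0.20 over 32 genes, at -0.24 and -0.11 (adjusted p = 0.0031; adjusted p = 0.41 with an estimated correlation). NK and cytotoxic markers had a median of 0.42, at 0.32 and 0.48 (adjusted p = 0.013; adjusted p = 0.54 with an estimated correlation). Stromal and endothelial markers had a median of 0.28, at 0.21 and 0.34 (adjusted p = 0.023), and dendritic cell markers 0.39, at 0.49 and 0.34 (0.025). Each of these had adjusted p = 0.33 with an estimated correlation. Plasma cell and secretory genes had a median of -0.15, at -0.30 and -0.26 (adjusted p = 0.025; adjusted p = 0.33 with an estimated correlation). Erythroid markers had a median of 0.29, at -0.01 and 0.31 (adjusted p = 0.036; adjusted p = 0.61 with an estimated correlation). Interferon response genes had a median of 0.20, at 0.11 and 0.34 (adjusted p = 0.044; adjusted p = 0.34 with an estimated correlation). For apoptosis genes the median, 0.02, and the mean, -0.14, differed in sign, the run medians were -0.16 and -0.03, and camera called the list down (adjusted p = 0.047; adjusted p = 0.41 with an estimated correlation; 0.073 with the run block). Without Btk KO of run 1 marginal zone markers (0.061) and apoptosis genes (0.064) also lost the call in Xid. B-1 markers, with a median of 0.31, at 0.52 and 0.07, passed with the run block alone (0.21 without it, 0.042 with it; adjusted p = 0.59 with an estimated correlation, without the block).

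The remaining lists did not pass in Xid. Medians were 0.28 for neutrophil markers, -0.13 for follicular B cell markers, 0.01 for T cell markers, -0.11 for glycolysis, -0.05 for MHC class II and antigen presentation, -0.05 for ribosomal proteins, 0.01 for NF-kB targets and 0.00 for germinal centre genes. They were -0.01 for oxidative phosphorylation, 0.16 for cytokine receptors and -0.13 for the unfolded protein response. The genes beside Btk on the X chromosome had a median of 0.14 over 7 genes and a camera direction of down (adjusted p = 0.95). Platelet markers, at -0.10 over 2 genes, and the Tec family list were too short to test. Camera called 14 of 27 lists in Xid, 8 up and 6 down, and 0 with an estimated correlation or with fry. Without Xid of run 2 it called 4, and without CBA of run 1 it called 5.

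**Figure D3:**
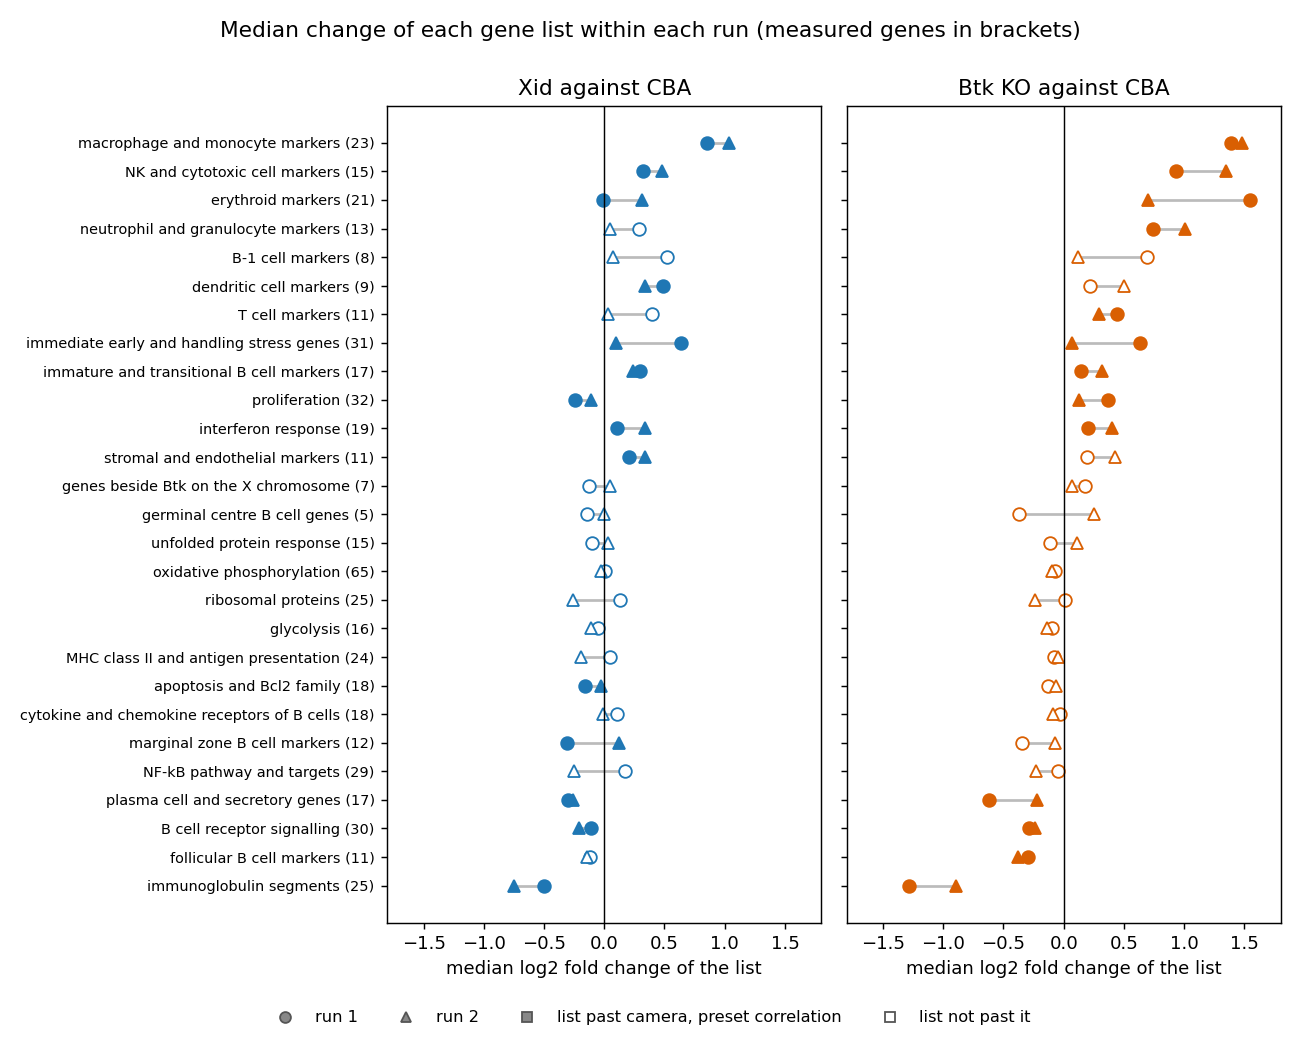
Points show the median log2 fold change of each tested list within run 1 (circle) and run 2 (triangle), for Xid (left) and Btk KO (right) against CBA; filled points are lists past camera with the preset correlation. Macrophage markers lie at 0.85 and 1.04 in Xid and at 1.39 and 1.48 in Btk KO, and immunoglobulin segments lie lowest in both panels.

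The comparison of Btk KO with CBA asks how the knockout line differs in the same cells. The knockout and other differences of that line, which had been crossed to CBA for 9 generations, cannot be told apart. Transcripts of macrophages, neutrophils, NK cells and red cell precursors were higher, and immunoglobulin segments and B cell receptor genes were lower. Each of these lists had adjusted p = 0.24 with an estimated correlation, and 0 erythroid genes passed over all genes in either limma fit. Mrc1 rose from 37.9 ± 0.707 to 267 ± 28.8 (change 2.63 ± 0.25, adjusted p = 0.025), Spic from 65.1 ± 15 to 346 ± 19.7 and Vcam1 from 337 ± 46.1 to 1650 ± 165. Camp, a neutrophil granule peptide, rose from 49.1 ± 13.7 to 298 ± 37.5, and S100a9 of neutrophils from 23.2 ± 8.98 to 223 ± 41.4. Mcoln2 fell from 226 ± 2.55 to 52.1 ± 7.21.

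Without the block, limma called 13 probe sets in Btk KO, 12 higher and 1 lower, with 658 at an unadjusted p under 0.05. By chance 373 would be expected there. With the run block limma called 166, 106 higher and 60 lower, and all 13 were among them. Besides those above, Tspan4 rose by 2.90, Abcc3 by 1.93, Cadm1, an adhesion molecule, by 2.12 and Slpi, a secreted protease inhibitor, by 1.52. The CBA mean of Tspan4, 14.4, lies near the floor, so the size of its change depends on the pseudocount. Vcam1 passed on a further probe set with a change of 2.27. Igf1 rose by 2.17 on 1 of its probe sets and was named after its values were seen. A probe set without a symbol rose by 4.79, from 93.1 ± 12.4 to 3040 ± 1900. All of these lay in the same direction in both runs. Ephx1 at -3.42 and the segments Igkv8-30 at -1.87 and Igkv2-112 at -1.71 filled the lower direction, with adjusted p of 0.052, 0.12 and 0.14 without the run block and 0.0053, 0.013 and 0.019 with it.

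Without the Btk KO array of run 1, limma called 12 probe sets, 7 of them shared with the 13. The calls depended on which single array was left out. Without Btk KO of run 2, the only Btk KO array is the one with the Gapdh ratio of 10.4, so the calls there may reflect RNA quality.

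Macrophage and monocyte markers had a median of 1.36 over 23 genes in Btk KO (adjusted p = 7.0e-25; adjusted p = 0.24 with an estimated correlation), at 1.39 and 1.48 within the runs. Over all genes 3 rose, and 17 with the run block, and 18 rose when adjusted over the list alone. Sirpa rose when adjusted over the list alone and, with the run block, over all genes (440 ± 1.91 against 140 ± 21.3; adjusted p = 0.0074), while further Sirpa probe sets differed by -0.63 and 0.55. Neutrophil markers had a median of 1.03 over 13 genes, at 0.74 and 1.01 within the runs (adjusted p = 7.1e-08; adjusted p = 0.24 with an estimated correlation). Over all genes 2 rose, and 4 with the run block, and 7 rose when adjusted over the list alone. S100a8 measured 448 ± 256 against 57.7 ± 9.62 (adjusted p = 0.052 without the run block and 0.012 with it). NK and cytotoxic markers had a median of 1.25 over 15 genes, at 0.93 and 1.35 within the runs (adjusted p = 4.7e-09; adjusted p = 0.24 with an estimated correlation). None rose over all genes without the block (0, with limma), 5 did with it, and 6 rose when adjusted over the list alone, among them Klra3 by 1.58, Eomes by 1.45 and Gzma, a granzyme, by 1.68. Over all genes these had adjusted p = 0.017, 0.044 and 0.012 with the run block.

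Erythroid markers had a median of 1.04 over 21 genes (adjusted p = 3.6e-12; adjusted p = 0.24 with an estimated correlation). The median was 1.55 in run 1, whose Btk KO array had the Gapdh ratio of 10.4, and 0.70 in run 2. None rose over all genes (0 in both limma fits), and 11 rose when adjusted over the list alone. Alas2, of heme synthesis, rose by 1.90, the nuclear protein gene Hemgn by 1.82, Epor, the erythropoietin receptor, by 1.40 and Hbb-b2, a globin, by 1.46 in that way. Over the list alone the block gave 13, and 0 without the array of run 1, where the median was 0.71. Hba-a1 measured 9710 ± 4730 against 4490 ± 1000.

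Immunoglobulin segments were lower in Btk KO, with a median of -1.16 over 25 genes (adjusted p = 3.6e-12; adjusted p = 0.24 with an estimated correlation). The medians were -1.28 in run 1 and -0.89 in run 2, and 23 were lower in both. Without the Btk KO array of run 1, which had the Gapdh ratio of 10.4, the median was -0.56 (adjusted p = 1.5e-07). Over all genes none passed without the block (0, with limma), and 13 fell and 1 rose with it. When adjusted over the list alone 6 fell and 1 rose. Igkv8-30 measured 260 ± 131 against 921 ± 218, Igkv8-19 measured 800 against 2090 and Igkv6-14 measured 1360 against 3290 (adjusted p = 0.013, 0.018 and 0.028 over all genes with the run block). The segment that rose was Igha, the constant region of IgA, at 2530 ± 856 against 689 ± 437 (0.0063 with the run block). The other Igha probe sets differed by 0.90 and -1.89 and did not pass.

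Genes of B cell receptor signalling had a median of -0.23 over 30 genes (adjusted p = 1.5e-04; adjusted p = 0.24 with an estimated correlation), at -0.29 and -0.24 within the runs. When adjusted over the list alone none passed without the block (0, with limma), and 4 fell with it. These were Nfatc1 at -1.77 (adjusted p = 0.0064 over all genes with the run block), the inhibitory co-receptors Cd72 at -0.97 and Cd22 at -0.66, and the phosphatase Ptpn6 at -0.73. With the block and without Btk KO of run 1 the count was 1. Follicular markers had a median of -0.34 over 11 genes, at -0.30 and -0.38 within the runs (adjusted p = 0.0035; adjusted p = 0.24 with an estimated correlation). Of these, 2 fell when adjusted over the list alone, Cxcr5, the receptor that guides B cells into follicles, by 0.90 (adjusted p = 0.044 over all genes with the run block) and Ccr6 by 0.96. The lineage markers Cd79a and Ms4a1 differed by -0.69 and -0.27, Cd3e by 0.35 and Lyz2 by 0.82, and none of these 4 passed.

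Other lists that passed in Btk KO were T cell markers with a median of 0.41, at 0.44 and 0.29 within the runs, or 0.66 without Btk KO of run 1 (adjusted p = 0.015; adjusted p = 0.43 with an estimated correlation) and interferon response genes with 0.20, at 0.20 and 0.40, or 0.39 without it (adjusted p = 0.021; adjusted p = 0.24 with an estimated correlation). In the interferon list Rsad2 rose by 1.82 when adjusted over the list alone (adjusted p = 0.040 over all genes with the run block). Immature and transitional markers had a median of 0.32, at 0.14 and 0.32 within the runs (adjusted p = 0.030, or 0.051 with the run block; adjusted p = 0.24 with an estimated correlation). Of these, 3 rose when adjusted over the list alone, Ly6d by 0.90, Il7r by 1.23 (just past the threshold over all genes with the run block, adjusted p = 0.050) and Vpreb1 by 0.99. Without the array of run 1 that had the ratio of 10.4, the following 3 lists lost the call. Immediate early genes had a median of 0.38, at 0.63 and 0.07 within the runs (adjusted p = 0.0037; adjusted p = 0.46 with an estimated correlation), and 0.12 without the array (adjusted p = 0.70). Proliferation genes had a median of 0.26, at 0.37 and 0.13 (adjusted p = 0.019; adjusted p = 0.45 with an estimated correlation), and 0.11 without the array (0.44). Plasma cell and secretory genes had a median of -0.20, at -0.62 and -0.22 (adjusted p = 0.045; adjusted p = 0.24 with an estimated correlation), and -0.15 without the array (0.14). Another 3 lists gained the call without it: ribosomal proteins at -0.32 (0.0039), dendritic cell markers at 0.48 (0.0053) and NF-kB targets at -0.30 (0.025). With all arrays these had adjusted p = 0.75, 0.24 and 0.60 with an estimated correlation.

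With all arrays the other lists did not pass in Btk KO. Medians were 0.50 for dendritic cell markers, 0.19 for stromal markers, 0.52 for B-1 markers, -0.12 for apoptosis genes, -0.18 for NF-kB targets, -0.17 for marginal zone markers and -0.11 for MHC class II and antigen presentation. They were -0.06 for ribosomal proteins, -0.06 for oxidative phosphorylation, -0.08 for glycolysis, 0.00 for germinal centre genes, -0.04 for the unfolded protein response (mean -0.02, camera direction up) and 0.12 for the genes beside Btk. Cytokine receptors had a median of -0.15 and a mean of 0.02, which differ in sign. Platelet markers stood at -0.05. With the run block fry called 2 lists, macrophage and monocyte markers and follicular markers (fry adjusted p = 0.034 each). Camera called 13 of 27 lists, 9 up and 4 down, and 0 with an estimated correlation or with fry without the block. Without Btk KO of run 2 it called 8.

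The comparison of Btk KO with Xid asks whether the knockout line and the line with the point mutation differ, which includes any other difference between the lines. Camp measured 298 ± 37.5 in Btk KO and 50.7 ± 7.92 in Xid, a difference of 2.42 ± 0.27 (adjusted p = 0.050 without the run block and 0.014 with it). Ctse on the probe set that fell in Xid, named after its values were seen, measured 703 ± 1.56 against 61.6 ± 42.6 (0.052 and 0.0097). Erythroid, NK and neutrophil transcripts and proliferation genes were higher in Btk KO than in Xid. These lists had adjusted p = 0.47, 0.52, 0.26 and 0.40 with an estimated correlation, and the erythroid median was 1.68 in the run whose Btk KO array had the Gapdh ratio of 10.4 and 0.26 in the other.

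Without the block, limma called 3 probe sets, none with exactly 1 symbol, with 269 at an unadjusted p under 0.05. By chance 373 would be expected there, so small p-values were not in excess in that fit. With the run block 545 had an unadjusted p under 0.05 (limma). The probe set without a symbol that rose in Btk KO was higher than in Xid by 5.24, and the one that fell most in Xid was higher in Btk KO by 2.95. The probe set with several symbols that rose in Xid differed by -4.85, with a Btk KO mean of 5.05 near the floor. With the run block 14 passed, 8 higher and 6 lower. Among them were S100a8 at 2.72, the interferon-inducible Ifi202b at 3.06 over an Xid mean near the floor (6.05), the glutamine transporter gene Slc1a5 at -3.13, the transcription factor gene Fli1 at -1.92 and Btk at -1.72. Other top ranked genes, S100a9 at 2.42, Wls at 1.72, Aldh9a1 at -1.93 and Ppie at -1.67, did not pass in either fit. Leaving out single arrays moved the count without the block both ways. It was highest without Btk KO of run 2, where the only Btk KO array is the one with the Gapdh ratio of 10.4.

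Of 27 lists, 8 passed, 5 up and 3 down, and 0 with an estimated correlation. Erythroid markers had a median of 0.97 (adjusted p = 3.5e-12; adjusted p = 0.47 with an estimated correlation), at 1.68 in run 1 and 0.26 in run 2. In that list 4 rose when adjusted over the list alone and 0 over all genes (limma), namely Klf1 by 1.20, Epor by 1.20, Alas2 by 1.44 and Car2 by 1.57. With the block and without Btk KO of run 1 the count over the list alone was 0, and without that array the median was 0.55. Proliferation genes had a median of 0.39 (adjusted p = 2.8e-09; adjusted p = 0.40 with an estimated correlation), at 0.54 and 0.25 within the runs. Rrm2 at 1.35, Top2a at 1.74, Ccnb2 at 0.82 and Stmn1 at 1.07 passed with the run block when adjusted over the list alone, and none over all genes. Without Btk KO of run 1 that count was 0 and the list median 0.21. Neutrophil markers had a median of 0.63, at 0.55 and 0.61 within the runs (adjusted p = 1.3e-07; adjusted p = 0.26 with an estimated correlation), and 5 rose when adjusted over the list alone, with 2 over all genes with the run block. NK markers had a median of 0.83, at 0.73 and 0.91 (adjusted p = 1.5e-07), and macrophage markers 0.56, at 0.66 and 0.50 (adjusted p = 3.5e-09). Both lists had adjusted p = 0.52 with an estimated correlation. For immunoglobulin segments, at -0.47 (adjusted p = 1.7e-05; adjusted p = 0.52 with an estimated correlation), the run medians were -0.78 and -0.19. Genes of B cell receptor signalling at -0.13, or -0.34 and -0.07 within the runs, and follicular markers at -0.23, or -0.15 and -0.31, each had adjusted p = 0.010 and adjusted p = 0.40 with an estimated correlation. T cell markers, at 0.48, or 0.25 and 0.44 within the runs, passed with the run block alone (adjusted p = 0.052 without it and 0.020 with it; adjusted p = 0.75 with an estimated correlation). Without Btk KO of run 1 the immunoglobulin list lost the call (0.56, median -0.03), as did the receptor list (0.37), and the NK median was 1.29. Without that array, immediate early genes at -0.26 (0.00069), ribosomal proteins at -0.23 (0.0067), T cell markers at 0.58 (0.0076) and the unfolded protein response at 0.23 (0.040) gained the call. With all arrays the first, second and last of these had adjusted p = 0.91 with an estimated correlation.

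The last comparison asks how far both lines depart from CBA in the same way. Vcam1, Mrc1, Spic, Tspan4 and Abcc3 were higher and Mcoln2, Ephx1 and Nfatc1 lower in each line, in both runs. With the run block, 17 probe sets were called higher in both lines, of 27 in Xid and 106 in Btk KO, and 7 lower in both, of 9 and 60. Simulated unchanged groups that shared simulated CBA arrays had a mean of 0.1 and at most 4 higher in both, and 0.06 and at most 2 lower, in 100 draws. Independent lists of these sizes would share 0.38 and 0.072. The simulation leaves out any effects and draws probe sets as independent, and the latter values leave out the shared CBA arrays. Part of the excess may therefore come from those arrays or from correlated probe sets. Without the block no probe set was called in both lines (limma, 0). For the mean of both lines against CBA, limma called 11 probe sets, 7 higher and 4 lower, and 144 with the run block.

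Across 7453 probe sets, which are not independent replicates, the log2 changes of both lines had a Pearson r of 0.633. Simulated unchanged groups that shared simulated CBA arrays gave a mean of 0.50 and at most 0.541 in 100 draws, since both comparisons use the same controls. The draws took arrays and probe sets as independent, whereas deviations of the real arrays were correlated within a run, at 0.31 to 0.44. The highest draw is therefore no firm limit for no change. The covariance was 0.118 against a simulated 0.0571, a difference of 0.061, and 72.3% of probe sets had the same sign against 66.7%. Within the runs r was 0.508 and 0.68, where unchanged groups gave means of 0.501 and 0.50 and at most 0.538 and 0.527. Run 1 alone thus did not exceed the draws. Those draws gave all arrays the same noise, whereas run 1 holds the Btk KO array with the Gapdh ratio of 10.4. The r of run 1 therefore cannot tell whether the lines share changes there. Xid of 1 run set against Btk KO of the other shares no array, and there the covariances were 0.0591 and 0.0884 and r was 0.239 and 0.286.

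**Figure D4:**
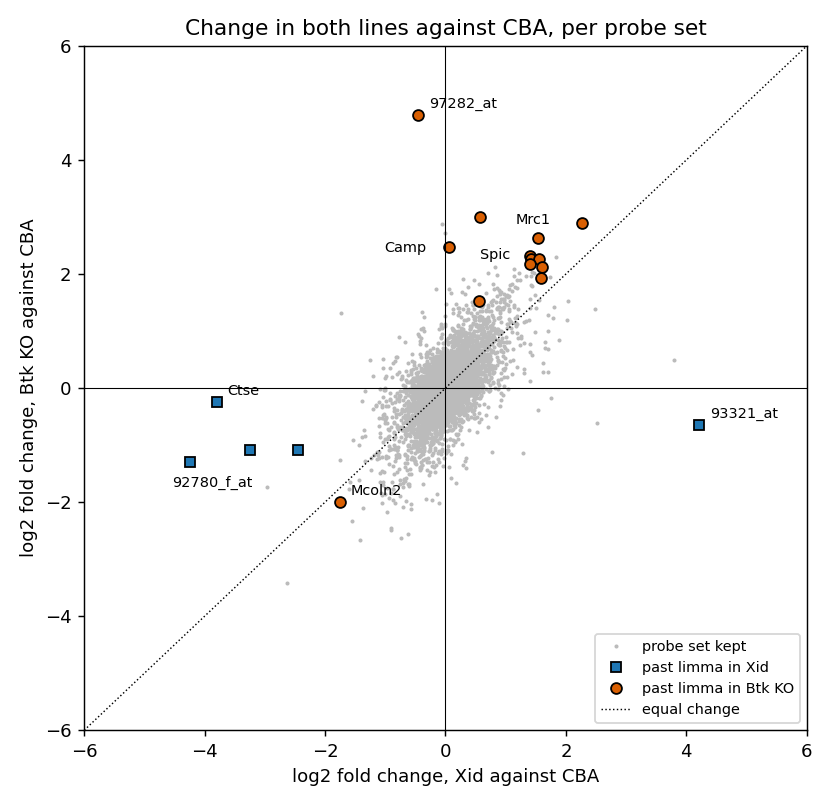
Each point is 1 of 7453 probe sets, with its log2 change in Xid (horizontal) and in Btk KO (vertical) against CBA; squares and circles mark the 5 and 13 probe sets past limma without the run block. Macrophage genes such as Mrc1 and Spic lie at the upper right, whereas a Ctse probe set changed in Xid (-3.80) and Camp in Btk KO (2.48).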

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

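Of the tests below, only that of Eif2s3x was written before its result was seen, and all others were chosen afterwards.

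Macrophage and monocyte markers were higher in both lines: of 23 measured, 21 in Xid and 22 in Btk KO were higher than CBA in both runs, and 1 of the 23 is also in another list. A lower share of B cells that raises every other cell type alike would move their markers equally. In Xid, macrophage markers exceeded T cell, erythroid and neutrophil markers by 0.663 (95% interval 0.46 to 1.1), which argues against it. NK, dendritic cell and stromal markers, with medians of 0.42, 0.39 and 0.28 against 0.90, were not in that test. The explanation is not excluded, since the bootstrap draws genes and not animals. Some compared markers also lie near the floor (Elane at 17.5 in CBA). In Btk KO the value of 0.36 (0.11 to 1.1, with 0.1 and 0.78 within the runs) cannot tell. Low RNA quality of the Btk KO array of run 1 is excluded as the cause, since the median in run 2 was 1.48 (1.3 to 1.6) in Btk KO and 1.04 in Xid. More macrophages in the preparations, for which the labels name no sort or gate, and higher expression of these genes per cell are hypotheses that were not tested. The probe sets of the list that were brightest in Btk KO were those of Hmox1 (864 in CBA, 1610 in Xid, 2850 in Btk KO), Ctsb (924, 1440, 2130) and C1qc (474, 1240, 1800), and intensities of different probe sets do not rank transcripts by abundance.

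Immunoglobulin segments were lower in Btk KO. The median in run 2 was -0.894 (95% interval -1.3 to -0.67), against -1.28 in run 1. This argues against RNA quality of the Btk KO array of run 1 as the whole cause. That explanation is not excluded, since the run 2 value rests on 1 CBA array and is smaller in size against both. The pooled median moves from -1.16 to -0.56 without the Btk KO array of run 1. For a lower share of B cells alone the values cannot tell: in run 2 the segments differed from 7 B lineage genes by -0.31 (-0.67 to -0.088), with those genes at -0.584. Against both CBA arrays, Btk KO of run 2 had a difference of 0.0815 (-0.15 to 0.35), with the segments at -0.561 and the B lineage genes at -0.642. The bootstrap draws genes and not animals, and run 2 holds 1 array per group.

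Eif2s3y, a Y-linked transcript on a probe set below the filter, gave 31.3 and 56.4 in the Btk KO arrays and at most 7.1 on the other 4, a signal in data outside the comparisons. Male cells in the Btk KO preparations remain open: Xist was lower than in CBA and Xid in both runs, with log2 differences from -0.64, the smallest drop, to -1.52, the largest, but Xid and CBA differed by -0.61 in run 2, and Xist still read 312.2 and 160.9 in Btk KO. Cross-hybridisation of the X-linked copy Eif2s3x is excluded, since Eif2s3x differed from CBA by at most 0.312 in 1 run and by -0.355 in the other. The Y-linked Kdm5d (6.2 and 2.9) and Uty (2.1 and 11.1) were near the floor in Btk KO.

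Other results were marked because a control departed from the other arrays or because the lines differed, and each is given as its value. The Gapdh 3' to 5' ratio was 1.61 in Xid of run 1 and 10.4 in Btk KO of run 1, and the beta-actin ratio was 3.61 in the latter. Btk KO minus Xid was 5.24 and 2.95 for a pair of probe sets without a symbol and -4.85 for a probe set with several symbols, whose Btk KO mean of 5.05 is near the floor. List medians of Btk KO minus Xid were 0.97 for erythroid markers, 0.39 for proliferation, 0.56 for macrophage and monocyte markers, 0.63 for neutrophil markers and 0.83 for NK and cytotoxic markers. They were -0.47 for immunoglobulin segments, -0.13 for B cell receptor signalling and -0.23 for follicular markers.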

How the results depend on the processing

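Among the lists and the genes named by the rule, no called result reversed its direction under any alternative. Other called probe sets were counted, and their directions were not compared across the alternatives. Counts follow in the order Xid, Btk KO, Btk KO against Xid, and the mean of both lines, which were 5, 13, 3 and 11. The run block pairs arrays of a chip lot and gave 36, 166, 14 and 144, keeping every call made without it, with 14, 12 and 9 lists (2 lost and 2 gained); besides those given beside their results, it changed no call printed here. The alternative chosen after seeing the data, the block without Btk KO of run 1, gave 76, 91, 12 and 165. Quantile normalization gave 7 in Btk KO and 1 in Btk KO against Xid. Of the 35 list calls it lost 5 and gained 0: in Xid receptor signalling (0.07), marginal zone (0.067), apoptosis (0.053) and interferon (0.053), and in Btk KO plasma cell genes (0.073). Median centring gave 8 in Btk KO and 7 for the mean and lost 1 list call, plasma cell genes in Btk KO (0.074); there the median change of all probe sets in Btk KO went from 0.01 to -0.103, and changes stand relative to it. A pseudocount of 1.5 gave 3 in Xid, and a pseudocount of 24 gave 8 in Xid and 8 in Btk KO against Xid. Without a filter Btk KO had 8. There 6 list calls were lost, in Xid marginal zone, apoptosis, interferon and erythroid, and in Btk KO immature markers and proliferation, and 2 were gained, stromal in Btk KO and T cell between the lines. At the 60th percentile Btk KO had 29, with 8 lists, and over the comparisons 7 list calls were lost and 1 gained. Without the intensity trend Btk KO and the mean had 0, and 2 list calls were lost. With only the groups compared, which leaves fewer degrees of freedom, the first 3 counts were 9, 0 and 0, and 3 list calls were lost and 1 gained. Camera with an estimated correlation and fry each called 0, 0 and 0 lists. With an estimated correlation, lists whose estimate lay below the preset 0.01 lost the call as well. The loss therefore does not by itself show correlation among their genes.

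Single arrays decide the counts. Where Btk KO of run 2 is left out, the only Btk KO array is the one with the Gapdh ratio of 10.4. Without either CBA array or Xid of run 1 all 4 counts were 0, without Btk KO of run 1 they were 9, 12, 5 and 14, and without Btk KO of run 2 they were 9, 145, 29 and 39. Without Xid of run 2 they were 1, 0, 1 and 0. Lists ranged from 4 (without Xid of run 2) to 14 in Xid, from 8 (without Btk KO of run 2) to 14 in Btk KO, and from 5 (without Btk KO of run 2) to 12 (without Xid of run 2) between the lines. The agreement of both lines ranged from 0.506 (without Btk KO of run 2) to 0.739 (without CBA of run 1), where unchanged groups gave means of 0.409 and 0.667 and at most 0.461 and 0.695. Without CBA of run 2 it was 0.678, which unchanged groups reached (at most 0.693). These draws leave out the correlation of arrays within a run and give all arrays the same noise, so their highest values are no firm limits. Except where fewer arrays or degrees of freedom explain it, the cause was not tested. Transcripts near a mean intensity of 19.8 are not measured reliably.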

Other observations

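Single genes not described above are given here by their values. Bcl2, which protects mature B cells from apoptosis, measured 417 ± 25.3 in CBA, 212 ± 58.9 in Xid and 180 ± 21.8 in Btk KO. In Btk KO it fell by 1.19 when adjusted over the list alone (adjusted p = 0.025) and over all genes with the run block (0.019), and in Xid it differed by -0.98 (0.073 over the list alone, and 0.012 with the run block). Bid, a pro-apoptotic partner, differed by -0.86 in Xid and -1.07 in Btk KO (0.16 and 0.054 over the list alone, and 0.033 and 0.0091 with the run block; over all genes 0.047 in Btk KO with the block). Bcl2l1, which also protects cells, differed by 0.10 and 0.92, the latter at 1.47 and 0.38 within the runs and 0.49 without Btk KO of run 1. The apoptosis list had medians of 0.02 and -0.12 and did not pass in Btk KO. Bcl6, the germinal centre repressor, fell in Xid from 193 ± 14.1 to 105 ± 16.4 when adjusted over the list alone (0.042) and measured 112 ± 25 in Btk KO.

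Jchain, which joins polymeric immunoglobulins, measured 1020 ± 199 in CBA, 451 ± 119 in Xid and 452 ± 72.5 in Btk KO, lower in both runs of each line (0.039 and 0.043 over the list alone). Dnajb9, a chaperone partner of the endoplasmic reticulum, measured 117, 215 and 234 and rose in each line when adjusted over the list alone (0.046 and 0.022; over all genes 0.040 in Btk KO with the run block). Txk, a Tec family kinase of T and NK cells, measured 14.8, near the floor, 54.2 and 81.2. It rose in both lines when adjusted over the list of T cell markers alone (0.047 and 0.0073; over all genes 0.017 in Btk KO with the run block), whereas Tec differed by 0.16 and -0.17. The Tec family list holds only these 2 measured genes, so its medians of 0.85 and 0.97 rest on Txk.

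Between arrays, Pearson r across probe sets was lowest for CBA of run 2 with Btk KO of run 1, at 0.877, and highest for Xid of run 2 with Btk KO of run 2, at 0.966. Xist measured 664 and 389.9 in CBA, 908.4 and 254 in Xid and 312.2 and 160.9 in Btk KO, for run 1 and run 2.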
